A study of Drosophila melanogaster with 3 samples.

How the data were processed

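Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of a transgenic line that expresses Blimp-1 with a C-terminal green fluorescent protein (GFP) tag, aged 10 to 12 h by the name of the source material. A separate age label holds a value that is not an age. Blimp-1 is the fly homologue of the zinc finger transcription factor PRDM1. Per the labels, the chromatin was sonicated to a size range of 200 to 800 bp, the tagged protein was precipitated with an antibody against GFP, and 3 samples were numbered as biological replicates of 1 group. There is no second group, so no difference between groups was tested. The comparisons are between replicates, between peaks and their own flanks, between peaks above and below the authors' threshold, and between lists of genes.

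The authors deposited 1 peak list per replicate, 1 list called on the 3 replicates together (the pooled list) and 1 list of pooled peaks that passed a threshold on the irreproducible discovery rate between replicates (the IDR-thresholded list). Per the deposited notes, reads were aligned to the dm6 build and each replicate was called against the same control alignment. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list held exactly 30000 peaks. All 9515 IDR-thresholded peaks were identical to, and at the same rank as, the 9515 pooled-list peaks of highest signal. The strength of a peak is the signal value in the authors' deposited lists, whose scale the sources used here do not define, and it was used only to rank and describe peaks within a list. The deposited lists also give a −log10 q-value per peak, which reached the same highest value in 100% of the IDR-thresholded peaks and was not used for ranking. Peak lists hold no read counts, so the depth of each replicate is unknown. Intervals on shares of peaks cover counting error only. Because the replicates share a control, noise from that control is common to them.

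Sequence came from the dm6 assembly (Release 6) and gene models from Ensembl release 115 on the same assembly, with pseudogenes and transposable elements left out. Coordinates are 1-based. A summit was assigned to 1 class in this order of priority: promoter (within 500 bp of an annotated transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron, intergenic. Shares were compared with 1000 circular shifts of the summits along their chromosome arms, which give a permutation p no lower than 0.001, and with the 20485 pooled-list peaks that had no IDR-thresholded summit within 100 bp, by a two-sided Fisher's exact test. Replicates were compared through each one's 9515 strongest peaks, with summits within 100 bp counted as matched. For the correlation of ranks, the strongest peaks of 1 replicate were matched to the full list of the other. The same 9515 strongest peaks of each replicate gave the mean ± SD (n = 3) printed beside a result.

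The Blimp-1 site was AGYGAAAG, where Y is C or T, on either strand. Its presence within 50 bp of a summit was set against a window of the same width centred 500 bp to the right of the same summit, by a two-sided exact McNemar test. The 95% interval of the centre-to-flank ratio came from 1000 resamples of 1 Mb blocks of the genome. The ratio of AGTGAAAG, with 0.5 added to both counts, was ranked among all 280 distinct rearrangements of its letters. The DREF, M1BP and homeodomain words were ranked in the same way after the data had been seen, with a word and its reverse complement taken as 1. The paired test was also run for 15 other patterns and for all 2080 6-mers, each family with Benjamini-Hochberg adjustment. The relation of the site to peak strength was tested over peaks with 100000 permutations. Peaks are not independent replicates.

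Of 13945 protein-coding genes, those with an IDR-thresholded summit within 1 kb of any of their TSSs were counted in 19 gene lists, with a two-sided Fisher's exact test against all other protein-coding genes and Benjamini-Hochberg adjustment over the lists. The lists cover processes of the embryo at this age, genes of the ecdysone response, markers of other cell types of the whole embryo, and broadly expressed genes. Of the 383 names and name stems in the lists, 380 matched a protein-coding gene. Symbols that had been renamed were followed to their current form after the peak lists had been read.

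The named genes are Blimp-1 and ftz-f1, the gene with the nearest TSS of each of the 10 strongest IDR-thresholded peaks that matched among the strongest peaks of all 3 replicates, the 3 members with the strongest TSS-proximal peak and the first member in alphabetical order with none for each list with adjusted p below 0.05 and for the ecdysone response, chitin and tracheal lists, the 5 genes with most summits in the gene body or within 1 kb of it, and the 3 most enriched and 3 most depleted 6-mers. This rule, the gene lists, the patterns, the tests and the main alternatives were fixed before the data were examined.

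Alternatives were other matching distances, numbers of peaks, promoter windows, site windows, flanks, patterns, backgrounds and gene assignments, the stronger part of the IDR-thresholded list, peaks matched in all 3 replicates, and peak sets made without each replicate in turn. Peaks with no other summit within 1 kb and random lists matched on the number of TSSs were added after the data had been seen.

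The tests were tested on simulated data. With words implanted at 6.06% of 9514 shifted summits, the share with the site rose by 5.99 percentage points and all 3 of the 6-mers inside the word were called among 2080, while 0 were called without implants. Shifted summits do not keep the base composition of the real ones, so this gives no rate of calls due to composition. With 59.3% of 9515 peaks copied between lists, 59.6% were matched. Over 100 draws on 13945 genes, 82.4% of the gene lists raised to 60% of genes with a peak were called, and 0.857% of the lists left at 25% were called. These draws gave each gene its peak independently. In the data 1 summit can count for several genes, so the rate of false calls there may differ. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.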

Results

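The binding of GFP-tagged Blimp-1 was mapped in whole embryos at 10 to 12 h of age, with 3 biological replicates of 1 group. The IDR-thresholded list held 9515 peaks with a median width of 357 bp and signal values from 208.1 to 25918.3. The depth of each replicate is unknown, since the peak lists hold no read counts.

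The replicates found largely the same places. Of the 9515 strongest peaks of a replicate, 77.5% of replicate 1 were matched within 100 bp in replicate 2, 76.0% of replicate 1 in replicate 3 and 81.8% of replicate 2 in replicate 3. The mean over the 6 ordered pairs was 78.4%, against 1.45% after circular shifts (permutation p = 0.001, the smallest that 1000 shifts can give). Ranks were compared between the strongest peaks of 1 replicate and their matches in the full list of 30000 peaks of another. Spearman's rho across these peaks was 0.872 for replicates 1 and 2 (8650 matched peaks). It was 0.857 for replicates 1 and 3 (8669) and 0.907 for replicates 2 and 3 (8994). Of the IDR-thresholded peaks, 6649 (69.9%) were matched among the strongest peaks of all 3 replicates and 79 (0.830%) in none. In the full lists of 30000 peaks, a comparison added after the data had been seen, 91.4% were matched in all 3 replicates, from 99.2% of the 952 strongest peaks to 81.8% of the 951 weakest. Among the 9515 strongest peaks of each replicate alone these shares were 99.1% and 1.26%, since the weakest peaks rank near the limit of that selection.

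The genes nearest the 10 strongest peaks included mol, Eip75B, verm and Blimp-1 itself. The strongest peak, 2L:14995356–14996463, was rank 1 in all 3 replicates and lay in an intron of mol (moladietz, a maturation factor of dual oxidase), 1792 bp downstream of the nearest TSS of that gene. The peak of rank 2, 2R:9121770–9122502, covered the promoter of GstE13, a glutathione S-transferase gene, with its summit 6 bp from the TSS. The peak of rank 3, 3R:9057024–9058055, lay in an intron of Kdm2, a histone demethylase gene. The peaks of rank 4 and 5 had Eip75B as the gene with the nearest TSS. Eip75B encodes an ecdysone-induced nuclear receptor. The peak of rank 4, 3L:17968141–17969355, lay in an intron of Eip75B, and the peak of rank 5, 3L:17936917–17937844, lay outside the gene, 24304 bp from its nearest TSS, with a CTTTCGCT within 50 bp of its summit. The other genes of the 10 strongest peaks were CG11537, CG31821, Mgat2 and verm, a chitin deacetylase gene. The summit assigned to CG31821 lay within the gene beat-Ib, so the nearest TSS need not mark the gene that a peak acts on.

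The peak of rank 6, 3L:5627541–5628851, was intergenic, with its summit 3033 bp upstream of the nearest Blimp-1 TSS. It ranked 4, 12 and 12 in replicates 1, 2 and 3 (mean rank 9.33, n = 3). Its window held no AGYGAAAG within 50 bp of the summit. In all, 10 IDR-thresholded summits had Blimp-1 as the gene with the nearest TSS, and 4 lay in the gene or within 1 kb of it.

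At ftz-f1, which encodes a nuclear receptor of the ecdysone cascade and is known as a gene repressed by Blimp-1, 16 summits lay in the gene (3L:18750607–18801309) or within 1 kb of it, which put it in place 34 of all protein-coding genes. The strongest of these, 3L:18770838–18772479, had rank 12 in the list (mean rank 13.0 over 3 replicates) and held AGTGAAAG within 50 bp of its summit, 5991 bp upstream of a TSS. A peak at 3L:18799929–18800719 held AGCGAAAG, 1032 bp downstream of the most distal TSS. A promoter peak at 3L:18765479–18766268, of rank 32, had its summit 146 bp upstream of a TSS. The genes with most summits were kirre with 41, Eip75B with 37, Hr4 with 27, and RapGAP1, Svil and cv-c with 26 each. These are long genes: kirre spans 394149 bp and held 1.03 summits per 10 kb. The density per 10 kb was 3.20 at Eip75B, 3.97 at Hr4, 3.13 at RapGAP1, 2.10 at Svil and 2.83 at cv-c. That of ftz-f1, 3.04 per 10 kb, lay within the range of these genes.

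**Figure D1:**
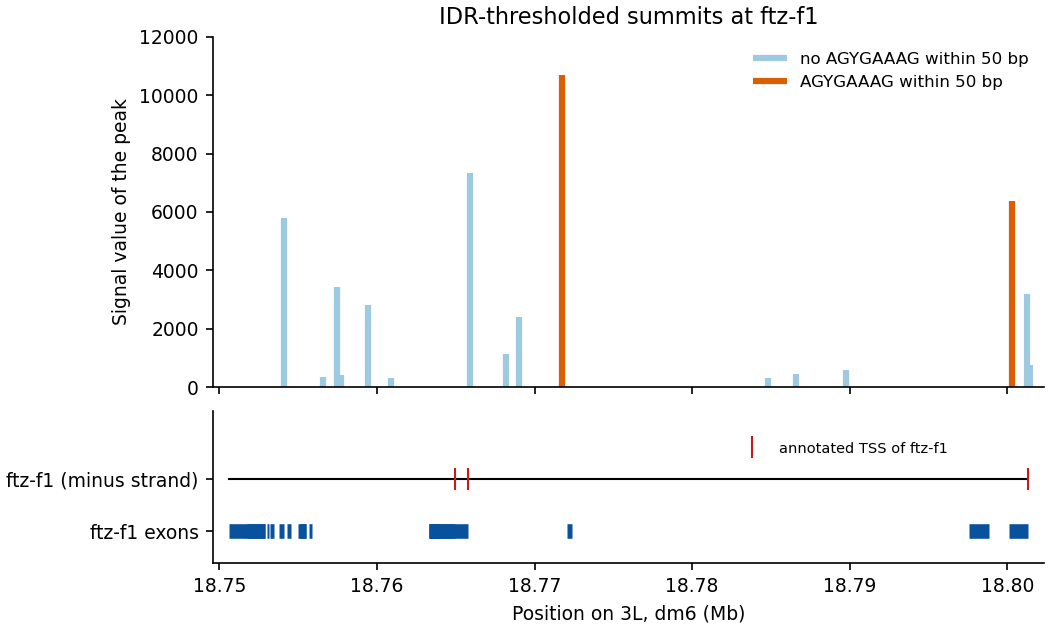
Signal value of each IDR-thresholded peak (y axis, no unit) at its summit position on 3L in Mb, dm6 (x axis), over ftz-f1 and 1 kb to each side, with the exons and annotated TSSs of ftz-f1 below. The 16 summits include some at the TSSs and others far inside the gene, and the strongest one, at signal 10686.3, holds a Blimp-1 site within 50 bp.

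Summits lay at promoters more often, and in coding exons less often, than shifted summits did, and introns held the largest share. Promoters held 2987 summits, or 31.4% (95% Wilson interval 30.5 to 32.3), against 13.4% after circular shifts (permutation p = 0.002, the smallest that these shifts can give in a two-sided test) and 19.6% of the pooled-list peaks below the threshold (odds ratio 1.88, Fisher's exact p = 1.51e-108). In the replicates the share was 32.7% ± 2.55 (SD, n = 3), with 30.1%, 32.6% and 35.2% in replicates 1, 2 and 3. Coding exons held 14 summits, or 0.147%, against 13.6% after shifts and 1.68% of the peaks below the threshold (odds ratio 0.0863, adjusted Fisher's exact p = 1.38e-39). In the replicates it was 0.203% ± 0.0684 (SD, n = 3). Summits had a median GC content of 34.7%, against 53.5% at random positions in coding exons. Random positions matched to the summits on GC content lay in coding exons in 6.91% of cases, a background added after the data had been seen. Introns held 47.0% of the summits, more than after shifts (39.4%) and fewer than below the threshold (51.6%). Intergenic sequence held 18.8%, 3′ UTRs 0.988% and 5′ UTRs 0.641%, and each was a lower share than below the threshold. Other exons held 1.05%, which did not differ from the share below the threshold (adjusted Fisher's exact p = 0.414). The promoter share was 44.5% in the 952 strongest peaks and 26.0% in the 951 weakest (a relation examined after the data had been seen; across peaks, Spearman's rho 0.100 and Pearson's r with log10 signal 0.112, permutation p = 1e-05 for both, the smallest that 100000 permutations can give).

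**Figure D2:**
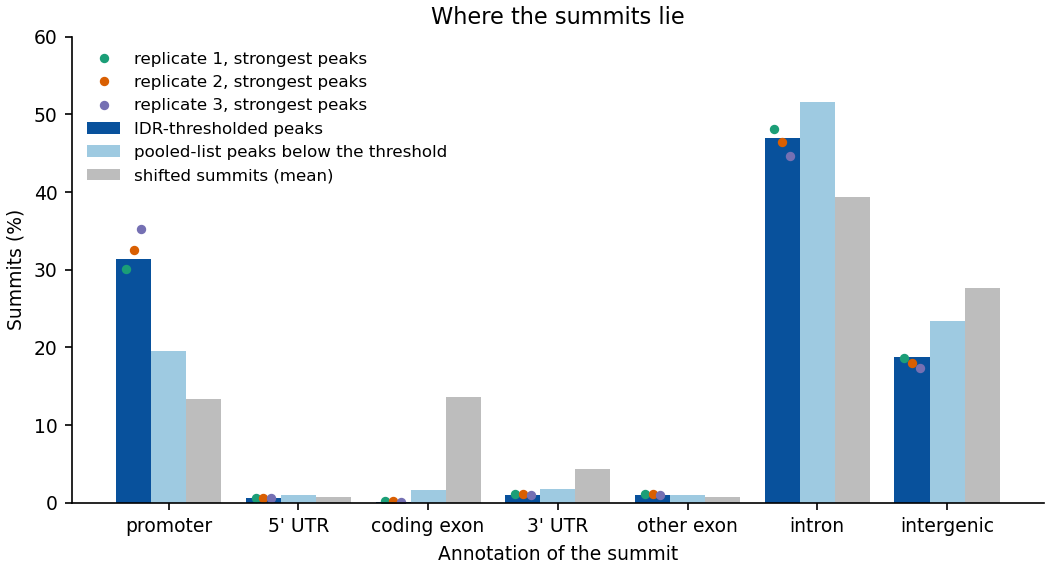
Share of summits in percent (y axis) by annotation class (x axis) for the IDR-thresholded list, the pooled-list peaks below the threshold and the mean of the circular shifts, with a point for the 9515 strongest peaks of each replicate. Promoters hold 31.4% of the IDR-thresholded summits against 13.4% of shifted ones, and coding exons 0.147% against 13.6%.

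The known recognition sequence of Blimp-1 was concentrated at the summits. AGYGAAAG lay within 50 bp of 600 summits, or 6.31% of peaks (95% Wilson interval 5.83 to 6.81), and in the flank of 91, or 0.956%. The centre-to-flank ratio was 6.59 (95% interval 5.34 to 8.30, exact McNemar p = 3.05e-95). In the replicates the share was 5.95% ± 0.819 (SD, n = 3) and the ratio 5.59 ± 0.950 (SD, n = 3). The share was 6.88%, 5.60% and 5.36% in replicates 1, 2 and 3. A longer form, GAAAGTGAAA with up to 1 mismatch, was at 13.1% of summits and in 2.52% of flanks. Most summits therefore held neither the exact site nor this form. AGTGAAAG had rank 2 among the 280 rearrangements of its letters. Rank 1 was GAAAGTGA, which shares AGTGA with it.

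**Figure D3:**
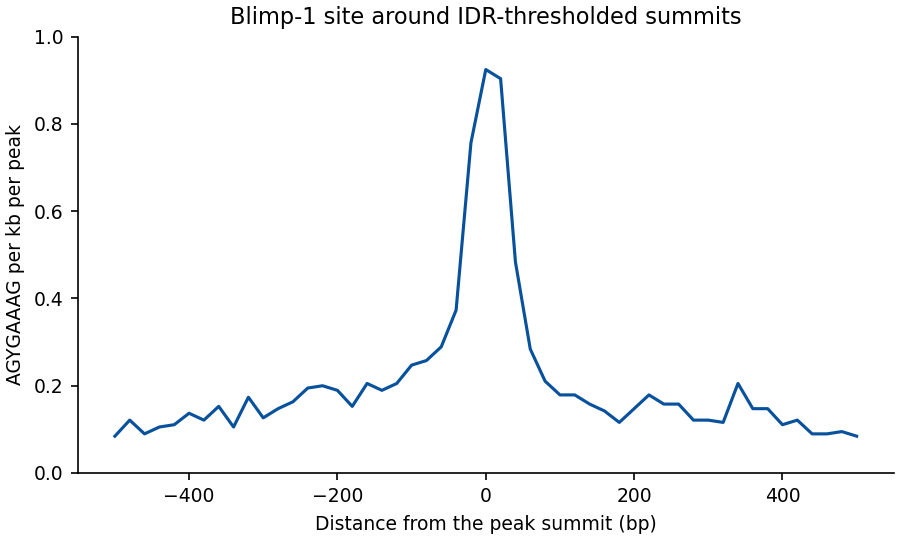
Density of AGYGAAAG on either strand, in sites per kb per peak (y axis), in 20 bp bins by distance from the summit in bp (x axis) over the 9515 IDR-thresholded peaks. The density is 0.925 at the summit, 0.121 in the bin 480 bp to the left and 0.0946 in the bin 480 bp to the right. The outermost bins, at 500 bp, were only partly covered by the search and read too low.

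Promoter peaks held the site less often than other peaks. It was at 4.92% of promoter summits and in 1.21% of their flanks (ratio 4.08, 95% interval 2.80 to 6.24, exact McNemar p = 1.59e-17), and at 6.94% of the other summits and in 0.843% of their flanks (ratio 8.24, 95% interval 6.31 to 11.3). The shares at the summit differed in a test added after the data had been seen (odds ratio 0.694, Fisher's exact p = 0.000158). In the replicates the ratio was 4.01 ± 0.821 (SD, n = 3) at promoters and 6.48 ± 0.955 (SD, n = 3) elsewhere.

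The strongest peaks held the site most often. It was at 12.3% of the 952 strongest peaks, at 5.57% of the next 951 and at 5.15% of the 951 weakest. Below the strongest bin, the share per bin of the ranking ranged from 4.10% to 7.98%, without an even fall. In the replicates the shares of the strongest and the weakest bin were 11.5% ± 1.50 and 4.28% ± 1.53 (SD, n = 3). Across the 9515 peaks, Spearman's rho between strength and presence of the site was 0.0697 and Pearson's r with log10 signal was 0.0887, each with a permutation p of 1e-05. Of the 100 strongest peaks 21 held the site, and 44 held the longer form.

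**Figure D4:**
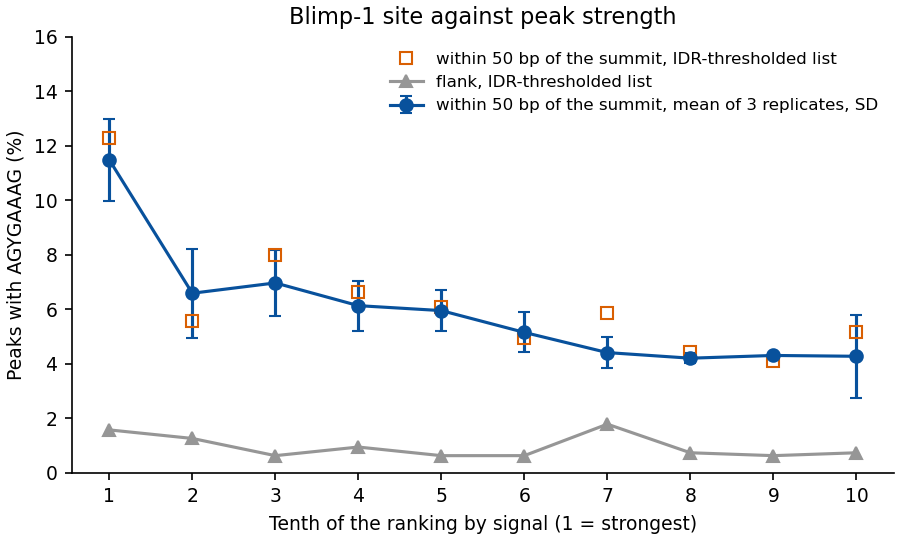
Share of peaks with AGYGAAAG in percent (y axis) in 10 bins of the ranking by signal, with 1 the strongest (x axis). Filled circles are the mean of the 3 replicates with SD, squares the IDR-thresholded list and triangles its flanks. The strongest bin stands apart at 12.3% of the IDR-thresholded list, and flanks stay between 0.630% and 1.79%.

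Of 15 other patterns, 3 were more frequent at summits than in flanks. These were the DREF site TATCGATA (ratio 3.24, adjusted exact p = 6.51e-05; replicates 3.75 ± 1.27, SD, n = 3), the M1BP site GGTCACAC (ratio 2.76, adjusted exact p = 0.000726; replicates 2.97 ± 0.508, SD, n = 3) and the homeodomain core TTAATTA (ratio 1.28, adjusted exact p = 0.000629; replicates 1.29 ± 0.132, SD, n = 3). DREF and M1BP are known to bind core promoters of broadly expressed genes. In the stronger part of the list only the homeodomain core stayed more frequent (1 of 15), with the DREF ratio at 1.83 and the M1BP ratio at 1.70. With the left flank the homeodomain core did not pass (ratio 1.16, adjusted exact p = 0.0502). Among the rearrangements of its own letters, a comparison added after the data had been seen, DREF had rank 3 of 592 and M1BP rank 11 of 1680. The homeodomain core had rank 35 of 35, against a median ratio of 1.78, so its excess was below that of other words of the same bases. At lower frequency were the CA repeat CACACACA (ratio 0.705, adjusted exact p = 0.000629) and the Tramtrack site GGTCCTGC (ratio 0.25, adjusted exact p = 0.0315), the latter at 4 summits. The Tramtrack call held in only 2 of 8 alternatives and was lost when any 1 replicate was left out (adjusted exact p from 0.0599 to 0.0938). Grainy head, POU, GAGA factor, Zelda, Trachealess/Tango, E-box, AP-1, GATA, Ftz-F1 and STAT92E patterns did not pass the test, with ratios from 0.810 to 1.16. Of 2080 6-mers, 408 were more and 990 less frequent at summits. The most enriched were ACTTTC (ratio 2.83), AGTGAA (2.37) and CTTTCA (2.25), which on either strand are parts of GAAAGTGA or AGTGAAAG. The most depleted were CCAGGA (0.190), AGGACG (0.244) and CAGGAC (0.289). Words of A and T alone were also enriched, such as TTTAAA (1.96) and AATATT (1.93), and the most depleted words are rich in G and C. Summits had a median GC content of 34.7%, against 42.6% at random positions. The 6-mers, the CA repeat and the Tramtrack site were not ranked among rearrangements of their letters. Their counts cannot separate base composition from a particular sequence.

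Genes of the ecdysone response, of chitin and cuticle assembly, of tracheal development and of ribosomal proteins were among those that had promoter-proximal peaks more often than other genes. Genes of cuticle structural proteins did not (18.0%), and Hox and segmentation genes had them less often, by the main background and distance. An IDR-thresholded summit lay within 1 kb of a TSS of 3467 of 13945 protein-coding genes, or 24.9%. In the ecdysone response list it was 18 of 26 genes (69.2%, odds ratio 6.83, adjusted Fisher's exact p = 1.5e-05; replicates 69.2% ± 3.85, SD, n = 3). Its strongest promoter-proximal peaks were at the nuclear receptor genes ftz-f1 (rank 32), Hr38 (rank 105) and Hr4 (rank 120), and br, which encodes the transcription factor Broad, had none. In the chitin and cuticle assembly list it was 21 of 31 genes (67.7%, odds ratio 6.38, adjusted p = 5.55e-06, Fisher's exact test). The peaks of highest signal there were at knk (rank 80), the chitin synthase gene kkv (rank 370) and the chitinase gene Cht7 (rank 1071), and Cht10 had none.

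Tracheal development genes had such a peak in 17 of 28 cases (60.7%, adjusted Fisher's exact p = 0.000284), led by stumps, an adaptor of fibroblast growth factor receptors, and by trh and dysf, which encode bHLH-PAS transcription factors. The receptor gene btl had none. Denticle and apical extracellular matrix genes had 12 of 20 (60%, adjusted Fisher's exact p = 0.00334), led by neo, nyo and CG16798. The peaks of neo and nyo held AGTGAAAG and AGCGAAAG, and cyr had no promoter-proximal peak. Cuticle tanning and wound response genes had 11 of 18 (61.1%, adjusted Fisher's exact p = 0.00372), led by kkv, Cad96Ca and grh (Grainy head), and b had none. Septate junction genes had 12 of 24 (50%, adjusted Fisher's exact p = 0.0166), led by nrv1, scrib and Atpalpha, and bou had none. The septate junction call held in only 2 of 10 alternatives. Notch pathway genes had 11 of 20 (55.0%, adjusted Fisher's exact p = 0.0101), led by the repressor genes E(spl)m7-HLH, E(spl)m3-HLH and E(spl)mdelta-HLH, and Delta had none. These repressor genes lie close together on 3R, between positions 25997621 and 26038019, and many other members of the list are E(spl) genes too. The test counts such neighbours as independent genes. Cytosolic ribosomal protein genes had 47 of 87 (54.0%, adjusted Fisher's exact p = 1.05e-07; replicates 59.4% ± 10.4, SD, n = 3), led by RpS28a, RpL36A and RpL34b, and RpL10 had none. In replicates 1, 2 and 3 the share of these genes was 48.3%, 60.9% and 69.0%. The RpS28a peak is the one of rank 9 whose nearest TSS is that of Mgat2. The peaks of RpL36A, RpL34b and E(spl)mdelta-HLH also lay nearer to the TSS of another gene, and kkv counts in both cuticle lists.

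Of 30 Hox and segmentation genes only hry, the pair-rule gene hairy, had a promoter-proximal peak (3.33%, odds ratio 0.104, adjusted Fisher's exact p = 0.0110; replicates 6.67% ± 3.33, SD, n = 3), and abd-A was the first without. By the nearest TSS at any distance, 19 of the 30 had a peak, 1.17 times the number in lists matched on territory (adjusted permutation p = 0.562). The other 10 lists did not pass. They were ecdysone synthesis (3 of 16), cuticle structural proteins (22 of 122), neuronal differentiation (4 of 24), muscle (11 of 28), hemocyte and fat body (5 of 24), gut and endoderm (5 of 18), germ line (5 of 15), innate immunity (8 of 26), heat shock (6 of 16) and proteasome (9 of 48).

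These calls depended on the background. Among the 5320 genes with any pooled-list peak within 1 kb of a TSS, 0 of the 19 lists passed Fisher's exact test after adjustment and 2 had an unadjusted p under 0.05. That background comes from the same precipitation, and the IDR-thresholded peaks are its strongest part. It kept 23 of 26 ecdysone response, 26 of 31 chitin and cuticle assembly and 7 of 30 Hox and segmentation genes. Of all protein-coding genes, it kept 38.1%. The test there asks whether genes with any peak had a strong one, so it cannot show that a list lacks an excess of peaks. The ecdysone response odds ratio fell there from 6.83 to 1.93, while that of Hox and segmentation stayed at 0.0888 with 7 genes left (unadjusted Fisher's exact p = 0.00873). Under 3 other settings 5 lists were higher, and not the same ones. Within 500 bp, septate junctions (odds ratio 2.33, adjusted Fisher's exact p = 0.127), tanning and wound response (2.47, 0.127), Notch pathway (2.59, 0.111) and Hox and segmentation (0.134, 0.0553) did not pass, and cuticle structural proteins were lower (12 of 122, 0.421, 0.00702). In the stronger part of the list, tracheal development (odds ratio 1.44, adjusted Fisher's exact p = 0.637), tanning and wound response (1.51, 0.651), Notch pathway (2.85, 0.0788) and Hox and segmentation (0.181, 0.160) did not pass. Against lists matched on the number of TSSs, septate junctions (ratio of shares 1.66, adjusted permutation p = 0.102), denticle and apical extracellular matrix (1.70, 0.0741) and tanning and wound response (1.81, 0.0630) did not pass.

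**Figure D5:**
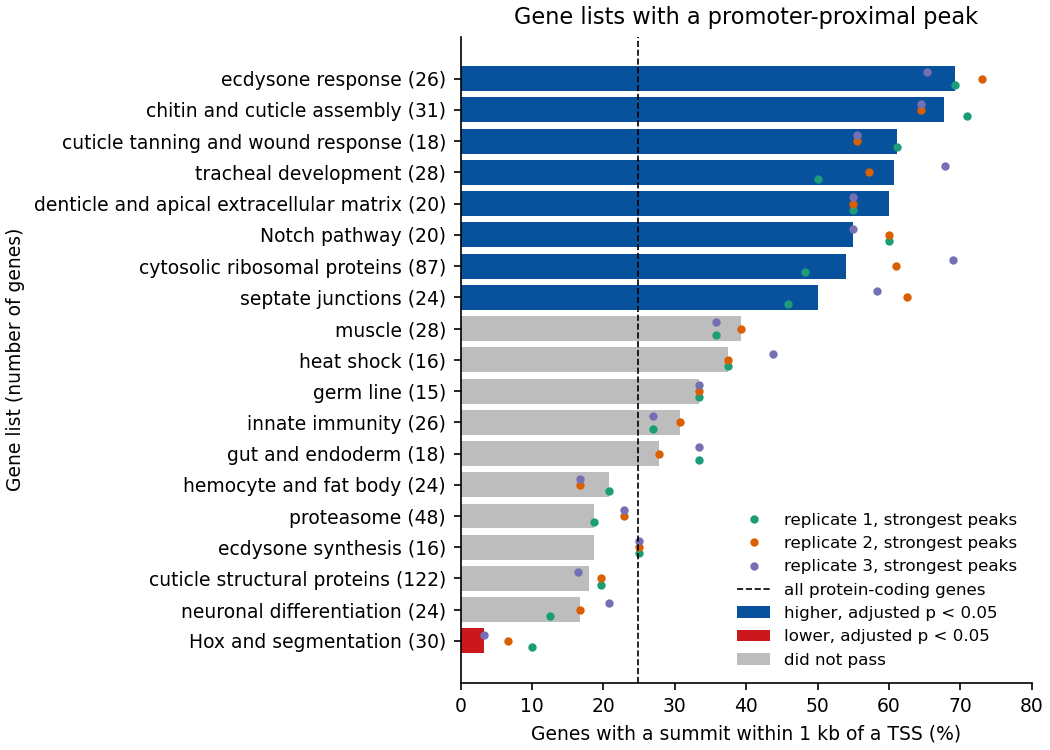
Share of the genes of each list with an IDR-thresholded summit within 1 kb of a TSS, in percent (x axis), by list with its number of genes (y axis). Bars are the IDR-thresholded list, points the 9515 strongest peaks of each replicate, and the dashed line all protein-coding genes at 24.9%. The ecdysone response list is highest at 69.2% and Hox and segmentation lowest at 3.33%.

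The X chromosome held 18.0% of the IDR-thresholded peaks on the X and the large autosome arms, against 19.2% of the peaks below the threshold (odds ratio 0.921, Fisher's exact p = 0.0106). Against the length of the arms the direction turned (odds 1.02, exact binomial p = 0.564). Chromosome 4 held 5 peaks, or 3.71 per Mb, against 65.6 to 78.3 per Mb on the other arms.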

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

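The peak upstream of Blimp-1 was picked out after the ranking of peaks and the summits in the Blimp-1 and ftz-f1 genes had been seen. The bounds of its tests were set after that look and before those tests were run, so the bound on the number of peaks at the locus was not blind to the data. The comparison with other named loci and the looser form of the site at that peak were chosen after the results were seen.

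Pooled-list peaks below the authors' threshold, which served as background, also held the Blimp-1 site above its level in their flanks, a signal in data that the main comparisons do not describe. It was at 2.37% of 20485 summits and in 0.981% of flanks (ratio 2.41, 95% interval 2.07 to 2.89, exact McNemar p = 2.12e-28), so this background is not free of the measured signal.

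The enrichment of the Blimp-1 site at summits was set against 2 technical explanations. Base composition of the summit windows is argued against for the form AGTGAAAG, at 398 summits, because it had rank 2 of the 280 rearrangements of its letters. The form AGCGAAAG was not ranked in this way. A single aberrant library is argued against, because the lowest ratio in peak sets made without a replicate was 5.10. With 1 group, no biological contrast was tested. Direct binding to the site may account for the excess as a hypothesis, but 6.31% of summits hold it and the rest stay unexplained.

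The excess of summits at promoters might come from unspecific enrichment of open chromatin there. The site ratio of 4.08 at promoter peaks, above 1 beyond its interval, argues against this only as the source of every promoter peak. The ratio cannot speak to the promoter peaks without the site. It fell short of the lower bound of 6.31 at the other peaks, which had been set as the level needed to exclude the explanation. From replicate 1 to replicate 3 the promoter share rose while the share of peaks with the site fell, a relation that was not tested. A mixture of bound and unspecifically enriched promoters cannot be told apart from binding without the sequence site, since 4.92% of promoter summits hold the site and no mock precipitation was analysed here.

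The strong peak upstream of Blimp-1 could come from extra copies of the locus on the transgene, if the line carries such copies, which the labels do not state. The 40 kb centred on Blimp-1 held 32 pooled-list peaks, more than 98.4% of windows on protein-coding genes and above the bound of 30 set for that explanation. The test does not separate it from dense binding: the same window held 33 peaks at ftz-f1, 37 at Hr4 and 45 at Eip75B, which are other loci. The IDR-thresholded summits with Blimp-1 as the gene with the nearest TSS had signal values from 237.2 to 12939.7. Copies of the whole locus would raise all of these together. They would not by themselves set this peak above its neighbours. Whether copies raised its rank in the list was not tested. Binding at an exact Blimp-1 site at the summit of this peak is argued against, since 0 sites lay within 50 bp of it, and the looser form was also absent there. The rest of the peak was not searched. Most strong peaks lack the exact site in that window, with 21 of the 100 strongest holding it, so its absence does not set this peak apart. Binding through another sequence or partner stays open and was not tested.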

How the results depend on the processing

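The alternatives with no other summit within 1 kb and with lists matched on the number of TSSs were chosen after the data had been seen. Replicate agreement (67.4% to 84.0%), the promoter share (19.6% to 41.9%), the site ratio (2.92 to 10.6), its rank (2) and its relation to strength (rho 0.0644 to 0.0817) kept their direction and side of the threshold under all alternatives run. The site ratio without a replicate was 5.10 to 6.71. The count of 3 enriched patterns fell to 1 in the stronger part of the list, where fewer peaks were tested, and 1181 of 32896 8-mers were enriched against 408 of 2080 6-mers. The 8 lists with more promoter-proximal peaks became 5 with summits within 500 bp, 5 in the stronger part of the list, 5 with lists matched on the number of TSSs and 0 among genes with a pooled-list peak. That last setting tests fewer genes, and the ecdysone response list is set against 65.1% of other genes rather than 24.8%. Its background comes from the same precipitation, so it compares peak strength among genes with a peak. The X odds ratio turned to 1.02 against arm lengths. Elsewhere the cause was not tested.

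Of 190 values for single lists, 149 kept direction and side of the threshold, 26 lost a call, 1 gained one (cuticle structural proteins within 500 bp, odds ratio 0.421) and 14 turned. Septate junctions kept the call in 2 of 10 alternatives, Hox and segmentation in 5, tanning and wound response in 6 and Notch pathway in 6. Beyond the settings above, septate junctions did not pass by nearest TSS (1.37), in peaks matched in all 3 replicates (2.56), without replicate 2 or 3 (2.32, 2.37) and in peaks with no other summit within 1 kb (2.67). Hox and segmentation did not pass in peaks matched in all 3 replicates (0.147), and Notch pathway in peaks with no other summit within 1 kb (2.01). None of the turned values passed the test. Odds ratios turned among genes with a pooled-list peak for muscle (0.652), hemocyte and fat body (1.34), gut and endoderm (0.668), Notch pathway (0.839), innate immunity (0.712) and proteasome (1.20). They turned for hemocyte and fat body in the stronger part of the list (1.05), ecdysone synthesis without replicate 1 only (range 0.890 to 1.11), germ line without replicate 3 only (range 0.987 to 1.40) and innate immunity for peaks with no other summit within 1 kb (0.677). By nearest TSS, ratios turned for cuticle structural proteins (1.08), germ line (0.824) and Hox and segmentation (1.17), and with matched numbers of TSSs for gut and endoderm (0.796).

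Of 120 values for single patterns, 94 kept direction and side, 10 lost a call, 2 gained one and 14 turned, none of the last past the threshold. Calls were lost for Tramtrack in 6 of 8 alternatives (0.182 to 0.286), M1BP in the stronger part (1.70) and in peaks matched in all 3 replicates (2.36), DREF in the stronger part (1.83) and the homeodomain core with the left flank (1.16). Grainy head passed within 100 bp (1.29) and Zelda with the left flank (0.701). The ratios that turned within 100 bp were GAGA factor (1.12), POU (0.888) and E-box (1.04). With the left flank they were GAGA factor (1.03), POU (0.841), E-box (1.04) and STAT92E (1.05). In the stronger part they were GATA (0.928) and STAT92E (1.06). Without a replicate AP-1 ranged from 1.05 to 1.10 and STAT92E, turned without replicate 2 only, from 0.988 to 1.05, and GAGA factor was 1.03 with no other summit within 1 kb. Unknown depth means that the absence of a peak at a gene cannot be read as absence of binding.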

Other observations

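All lists and tests in this part were chosen after the main results had been seen. Of 14 further gene lists, 5 had promoter-proximal peaks more often than other genes and 1 less often. Wnt pathway genes had 12 of 19 (63.2%, adjusted Fisher's exact p = 0.00318; replicates 59.6% ± 3.04, SD, n = 3), including Axn, nkd and sgg. The peak of Axn is the one of rank 9 also counted for RpS28a and Mgat2. EGFR and FGFR signalling genes had 13 of 21 (61.9%, adjusted Fisher's exact p = 0.00318), including drk, spi and aos. Of the 21, 6 also stand in the tracheal development list. Hippo pathway genes had 9 of 14 (64.3%, adjusted Fisher's exact p = 0.00959), including Diap1, ds and yki. Osiris genes, a family clustered in the genome, had 13 of 25 (52.0%, adjusted Fisher's exact p = 0.0111), and nuclear receptor genes 11 of 20 (55.0%, adjusted Fisher's exact p = 0.0111), of which 14 also stand in the lists above. Cytochrome P450 genes had 10 of 83 (12.0%, adjusted Fisher's exact p = 0.0115). Among genes with a pooled-list peak, where the test compares peak strength, 0 of the 14 passed Fisher's exact test after adjustment. The lists that did not pass were glutathione S-transferases (7 of 35), mitochondrial ribosomal proteins (21 of 73), translation factors (15 of 52), respiratory chain and ATP synthase (16 of 80), vacuolar ATPase (6 of 33), JAK/STAT (2 of 9), Dpp (6 of 14) and Hedgehog (1 of 10).

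Genes of the cytosolic ribosomal protein list had a promoter-proximal peak more often than those of the proteasome list (47 of 87 against 9 of 48, odds ratio 5.09, Fisher's exact p = 5.94e-05). Both lists were made from name stems, so they also hold paralogues, such as Prosalpha1R beside Prosalpha1 and RpS10a beside RpS10b. How these weigh on the odds ratio was not tested. Among genes with a pooled-list peak the difference did not pass (47 of 60 against 9 of 13, odds ratio 1.61, Fisher's exact p = 0.485). The peaks at these ribosomal protein promoters held the Blimp-1 site in 1 of 53 cases. Over the 8 lists with more promoter-proximal peaks, 5 of 195 such peaks held the site (2.56%), against 188 of 3374 (5.57%) at other genes (odds ratio 0.446, Fisher's exact p = 0.0731). In the ecdysone response list it was 0 of 32, and in the chitin and cuticle assembly list 0 of 28. These counts are of the exact site. Of the leading peaks of the ecdysone and chitin lists, those at ftz-f1, Hr4, knk and Cht7 held the longer form with up to 1 mismatch. Those at Hr38 and kkv did not. In the other called lists, the leading peaks at neo, nyo, RpS28a and RpL36A held it. Those at CG16798 and RpL34b did not, nor did any leading peak of the tracheal, septate junction, tanning or Notch lists. The longer form was at 44 of the 100 strongest peaks and at 13.1% of all summits.

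The DREF site was enriched at promoter summits (1.44% against 0.234% in flanks, ratio 6.14, adjusted exact p = 2.24e-06) and was at 0.184% of other summits against 0.153% of their flanks (ratio 1.20, adjusted exact p = 1).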
